A study of Danio rerio with 16 samples.

How the data were processed

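Whole zebrafish (Danio rerio, wild-type AB strain) were exposed as embryos to perfluorobutanoic acid (PFBA) at 0, 4, 40 or 400 ppb from about 1 to 72 hours post fertilization (hpf), per the labels' protocols. Total RNA of 4 biological replicates per dose, each a pool of 45 to 50 fish, was labelled with Cy3 and hybridised to 16 Agilent arrays, so that a replicate number stands for a separate pool. Per the file headers, an array held 180880 spots, of which 4854 were controls, and 128291 distinct probes, with 46091 probes on more than 1 spot. Images were read with Agilent Feature Extraction 12.0 per the submitters' processing notes. The headers of the scanner files name version 11.0.1.1 for the 4 arrays of replicate 1 and 12.0.3.1 for the rest.

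The scanner files deposited by the authors give for each spot a processed signal intensity, background-subtracted by Feature Extraction per the file headers, with quality calls. The value table deposited by the authors holds the same processed signal intensity rounded to 3 digits: 100% of spots on each array lay within 0.6% of it, so it is on the linear scale and not centred, and its array medians ran from 101 to 219. The authors' 3 deposited tables of changed probes, 1 per dose, give a gene symbol, a fold change and its log2; how arrays were scaled and tested for them is not given in the sources used here.

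From the scanner files, log2 of the processed signal minus the array's 75th percentile of it was taken as the normalized log2 signal. Control spots and spots called outliers by the scanner software were left out, no spot was saturated, and spots of 1 probe were averaged. A probe was kept if it was well above background on at least 4 of the 16 arrays, whatever their group, which left 101957 probes (79.5%), of which 81629 were so on all arrays. Every comparison was fitted on all 16 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and the data.table package (1.17.8), with Benjamini-Hochberg adjustment within the comparison, and a probe was called at an adjusted p under 0.05 with no limit on the fold. The 8 tests were each dose against 0 ppb, the 3 pairs of doses, any dose (moderated F test) and a slope over dose rank. With 4 arrays per group, the number of arrays limits the precision. Each standard error is that of the limma fit, and n = 4 arrays per dose.

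Probes were named through their RefSeq accession, without version, in the RefSeq gene table of assembly GRCz12tu, which was used for names alone. It named 39952 of 42900 RefSeq probes (93.1%), or 31.1% of all probes, and 63407 kept probes stayed unnamed here. A gene was represented by its kept probe with the highest mean signal, which gave 13233 genes. Gene lists, 45 in all, were written for the tissues, hormone axes and stress responses of a whole 72 hpf fish, and tested with camera at a preset correlation of 0.01, 2-sided, with adjustment over the 45 lists within a dose. Camera compares a list with all other genes. An estimated correlation and fry, which asks whether a list's genes moved on balance 1 way, were alternatives. The mean of a list is over its genes, with the SD between genes.

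Samples, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took, for each dose against 0 ppb, the 10 called genes with the largest rise and the 10 with the largest fall whose 4 exposed arrays all lay on the same side of the control mean, and up to 3 called members of each list by smallest p. Where fewer than 10 genes were called at a dose, genes with the smallest unadjusted p filled the set up to 20, as values that did not pass. It also took the top 2 members of each list past the threshold, the 5 genes with the smallest p for any dose and for the trend, up to 10 genes on all 3 of the authors' lists, and 6 reference genes. It named 116 genes. The fixed plan asked for the mean spot signal in the normexp alternative, for which the median spot and background signals of the spots were used, with an offset of 50.

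Per the file headers each slide held the 4 arrays of 1 replicate number, 1 per dose, so slide, replicate and extraction version run together, and positions 1 to 4 held 0, 4, 40 and 400 ppb on each of the 4 slides. Replicate 1 was scanned on the first day, replicates 2 and 3 on the second and replicate 4 on the third. Deviations from the group means, over all kept probes, correlated between 400 ppb and 0 ppb arrays of the same number at 0.46, 0.47, 0.38 and 0.40 for replicates 1 to 4, and between 4 ppb and 0 ppb at 0.37, 0.56, 0.33 and 0.28, all over 0.1, while those of 40 ppb and 0 ppb gave -0.16, 0.71, 0.22 and -0.20. On 14 of the 16 arrays the deviation was most like that of an array of the same slide. Values with the replicate number, here also the slide, as a block are therefore given beside a result where they change it. No 2 arrays held identical values, and correlations between arrays over probes ran from 0.950 to 0.992.

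The fit and the list test were tested on simulated data made from the real arrays for 400 ppb against 0 ppb (101957 probes). Of 66 probes shifted by 0.5 log2 0% were called, of 67 shifted by 1 35.8%, and of 67 shifted by 2 79.1%, with median estimates of 0.47, 1.03 and 1.97, and 4 unchanged probes were called. A shifted list was recovered (adjusted p = 6.03e-46) and 0 of 44 unchanged lists passed. The simulated probes were drawn independently, with no correlation between genes and no slide differences. The 0 of 44 therefore does not show how often camera at the preset correlation passes unchanged lists on the real arrays. Alternatives were normexp background correction, quantile and median scaling, the deposited value table, other filters on dim probes, trend and robust variances, array weights, only the groups compared, blocks for replicate and scan day, other thresholds, an unmoderated test, other dose scales and the leaving out of each array. Fits without 0 ppb replicate 4 and 40 ppb replicate 1 were added after seeing the data. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.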

Results

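Perfluorobutanoic acid (PFBA) is a perfluoroalkyl acid with a short carbon chain. Zebrafish were exposed to it at 0, 4, 40 or 400 ppb through embryonic development, and RNA of whole fish was measured at 72 hpf to find which genes respond at which dose. The 4 groups held 4 pools of 45 to 50 fish each, and each pool was read on 1 array. Between 73.8% and 89.0% of spots per array were well above background, and median processed signals ran from 108 to 231. In all 101957 of 128291 probes were tested, among them probes of 13233 named genes. Fold changes below are log2 values against 0 ppb with their SE (n = 4 per group).

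The first principal component of the 16 arrays (38.5% of the variance) set 2 arrays of different doses and slides apart, 40 ppb replicate 1 at -229 and 0 ppb replicate 4 at -212. These had the largest shares of spots well above background, 89.0% and 85.2%, against 73.8% to 82.9% on the rest, and over probes their deviations from their groups correlated (r = 0.684).

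**Figure D1:**
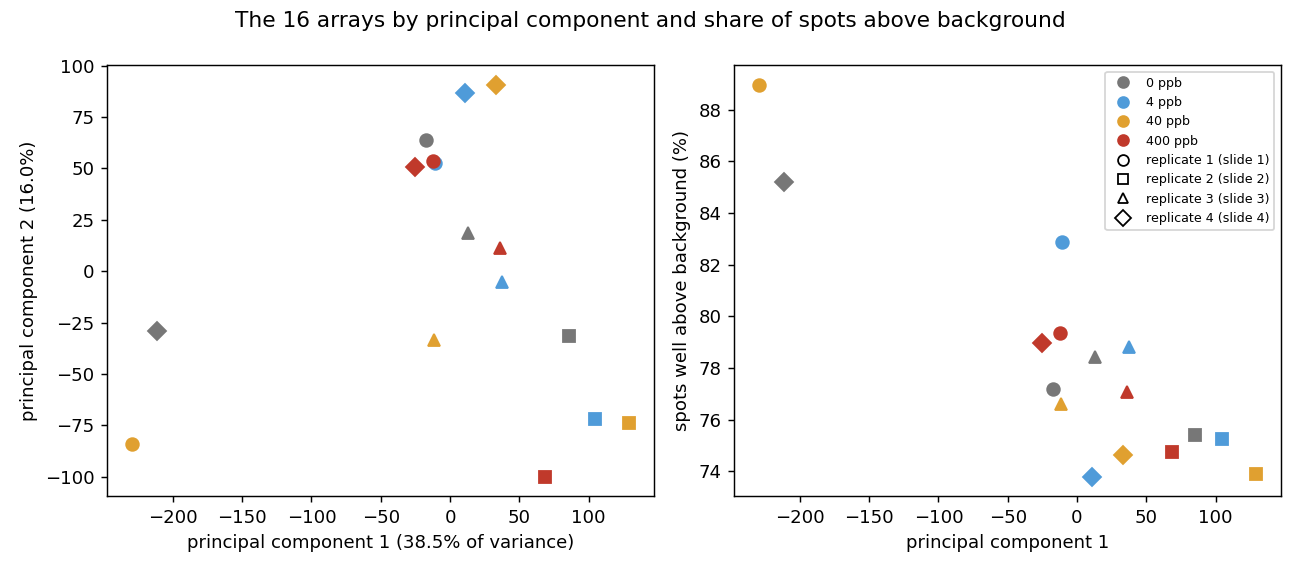
Left, the 16 arrays on principal components 1 (38.5% of the variance) and 2 (16%); right, component 1 against the percent of spots well above background; colour gives the dose of PFBA in ppb and shape the replicate, which is also the slide. The arrays of 40 ppb replicate 1 (89.0% of spots) and 0 ppb replicate 4 (85.2%) lie apart from the rest at the left of both plots.

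At 400 ppb, genes of the digestive organs rose. Of 28 measured genes of the exocrine pancreas and its enzymes, 27 were higher than at 0 ppb, with a mean change of 1.3 ± 0.74 (SD between genes; adjusted p = 1.67e-39, and 0.0202 with an estimated correlation). The 4 slides gave 1.46, 1.24, 1.23 and 1.29. Chymotrypsinogen ctrb.2 changed most, by 3.15 ± 0.38 (adjusted p = 0.00313, 8.9-fold), from -0.88 ± 0.52 (normalized log2 signal, SD, n = 4) at 0 ppb to 2.27 ± 0.18. The chymotrypsin-like ctrl rose by 1.70 ± 0.22, the pancreatic amylases amy2a and amy2al2 by 1.98 ± 0.25 and 1.98 ± 0.25, and sycn.2, which codes for the zymogen granule protein syncollin, by 2.09 ± 0.26 (adjusted p = 0.00361 to 0.00475). In all 18 genes of this list were called over all probes tested, and 23 adjusted over the list alone, all of them higher. Each of the genes named here was higher on 4 of 4 slides.

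Intestinal genes rose with them: 32 of 37 were higher, by 0.60 ± 0.72 on average (adjusted p = 9.71e-21, and 0.0202 with an estimated correlation; slides 0.71, 0.65, 0.57 and 0.45), with 12 called and 18 adjusted over the list alone. The brush border metalloproteases mep1a.1 and mep1a.2 rose by 1.91 ± 0.22 (adjusted p = 0.00243) and 2.2 ± 0.30 (adjusted p = 0.0051). The chitinase chia.2 rose by 1.64 ± 0.20 (adjusted p = 0.00313). Among genes on no list, the astacin proteases c6ast4 and c6ast3 rose by 2.89 ± 0.31 and 2.1 ± 0.24 (adjusted p = 0.00243 for both) and the intestinal sphingomyelinase enpp7.1 by 2.52 ± 0.39 (adjusted p = 0.0116; 0.0549 without 0 ppb replicate 1). The aminopeptidase anpepb.1 rose by 1.39 ± 0.19 (adjusted p = 0.00521). Bile acid genes rose by 0.36 ± 0.40 (11 of 14 higher, adjusted p = 4.4e-07, and 0.0202 with an estimated correlation; slides 0.38, 0.34, 0.40 and 0.32). The ileal bile acid binding protein fabp6, also an intestinal gene, was the 1 called member of the bile acid list over all probes (1.33 ± 0.19, adjusted p = 0.0069), with 7 adjusted over the list alone. The rate-limiting enzyme of bile acid synthesis, cyp7a1, gave 0.91 ± 0.19 and did not pass (adjusted p = 0.0573, and 0.0062 with the replicate block).

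Genes of xenobiotic metabolism rose by 0.37 ± 0.50 on average, 42 of 52 being higher (adjusted p = 1.27e-13, and 0.0202 with an estimated correlation; slides 0.42, 0.43, 0.35 and 0.27). Over all probes 4 were called, and adjusted over the list alone 19 higher and 1 lower. The cytochromes P450 cyp3a65 and cyp2n13 rose by 1.5 ± 0.18 and 1.68 ± 0.21 (adjusted p = 0.00324 for both). A further P450, cyp3c4, rose by 1.26 ± 0.20 (adjusted p = 0.0121; 0.0563 without 0 ppb replicate 1), with 1 other probe of the gene going the other way.

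The liver list shifted by 0.26 ± 0.46 (37 of 52 higher, adjusted p = 7.35e-07), a call lost at adjusted p = 0.256 with an estimated correlation; 5 members were called and 8 adjusted over the list alone. The fetuin ahsg2 rose by 1.94 ± 0.22 (adjusted p = 0.00243) and the tyrosine aminotransferase tat by 1.23 ± 0.17 (adjusted p = 0.0051). The tryptophan dioxygenase tdo2b rose by 1.68 ± 0.27 (adjusted p = 0.0142; 0.0663 without 0 ppb replicate 1 and 0.0522 without 400 ppb replicate 2). The lipoprotein list moved by 0.22 ± 0.35 (adjusted p = 0.000413, and 0.42 with an estimated correlation). Apolipoprotein apoda.2 rose by 1.15 ± 0.13 (adjusted p = 0.00282). The deiodinase dio1, an enzyme of thyroid hormone activation, rose by 0.85 ± 0.11 (adjusted p = 0.0051). Transthyretin ttr, a carrier of thyroid hormone made in the liver, rose by 1.37 ± 0.23 (adjusted p = 0.0164; between 0.0512 and 0.0652 without 0 ppb replicates 1 and 3 or 400 ppb replicates 2 and 4). The thyroid list itself did not pass (0.14 ± 0.53, adjusted p = 0.0642).

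A further 13 lists passed upward, each losing its call with an estimated correlation. Kidney and ionocyte genes moved by 0.17 (adjusted p = 0.000413, and 0.127 with an estimated correlation) and fatty acid oxidation, many of whose genes are targets of PPAR receptors, by 0.13 (0.00128, and 0.42). Skin genes moved by 0.13 (adjusted p = 0.00128, and 0.599 with an estimated correlation), yolk use by 0.22 (0.00139, and 0.357) and endocrine pancreas by 0.12 (0.00704, and 0.423). The calls for the other 8 also ended when 1 array was left out. Hypoxia moved by 0.10 (adjusted p = 0.011, and 0.599 with an estimated correlation) and ended without 400 ppb replicate 4 (adjusted p = 0.0755, mean 0.0503). Heat shock moved by 0.23 (adjusted p = 0.011, and 0.369 with an estimated correlation) and ended without 0 ppb replicate 4 or 400 ppb replicate 2 (adjusted p = 0.0663 to 0.103, mean 0.217 to 0.138). Macrophages moved by 0.09 (adjusted p = 0.0169, and 0.36 with an estimated correlation) and ended without 0 ppb replicate 2 or 400 ppb replicate 1 (adjusted p = 0.0509 to 0.102, mean 0.0714 to 0.049). Photoreceptors moved by 0.09 (adjusted p = 0.0219, and 0.622 with an estimated correlation) and ended without 0 ppb replicate 3 or 400 ppb replicate 4 (adjusted p = 0.112 to 0.131, mean 0.0324 to 0.0285). Steroid hormones moved by 0.13 (adjusted p = 0.0295, and 0.456 with an estimated correlation) and ended without 0 ppb replicate 2 or 400 ppb replicate 4 (adjusted p = 0.0586 to 0.0877, mean 0.0987 to 0.0851). Oxidative stress moved by 0.10 (adjusted p = 0.0326, and 0.622 with an estimated correlation) and ended without 0 ppb replicate 1 or 400 ppb replicates 2, 3 and 4 (adjusted p = 0.0529 to 0.109, mean 0.0904 to 0.0591). Immediate early genes moved by 0.09 (adjusted p = 0.0436, and 0.622 with an estimated correlation) and ended without 0 ppb replicates 2 and 4 or 40 ppb replicate 1 or 400 ppb replicates 1 and 2 (adjusted p = 0.05 to 0.386, mean 0.107 to 0.0637). The hatching gland list, 0.40 ± 0.76 with 7 of 12 genes higher (adjusted p = 0.0246, and 0.451 with an estimated correlation), ended without 0 ppb replicate 2 or 400 ppb replicate 4 (adjusted p = 0.0586 to 0.0868, mean 0.383 to 0.365) and with the replicate block (0.13). Without the 2 arrays standing apart the heat shock (adjusted p = 0.126, mean 0.217) and immediate early (0.447, mean 0.107) calls ended, and with the block as well those of immediate early genes (0.112), skin (0.124) and hatching gland (0.283). Leaving out these 2 arrays raised the means of steroid hormones to 0.25, macrophages to 0.18, photoreceptors and hypoxia to 0.15 and skin to 0.21. Immediate early genes also ended with quantile scaling (adjusted p = 0.179) and steroid hormones with normexp (0.0596).

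Single called members of these and other lists were the gluconeogenic pck1 (1.32 ± 0.23), the kinase pdk2b (1.11 ± 0.19), the fatty acid binding fabp2 (0.80 ± 0.14) and the carboxypeptidase cpa5 (1.18 ± 0.21), which stands on both the macrophage and the exocrine pancreas list. Others were the granulin grna.2 (1.16 ± 0.21), the cathepsin ctsl.1 (1.4 ± 0.25), the lipoprotein receptor scarb1 (0.68 ± 0.13), the sulfate transporter slc13a1 (0.71 ± 0.14), ifitm1 (0.82 ± 0.15), mybpc2a (0.93 ± 0.19) and lpin1a (0.65 ± 0.13). Their adjusted p ran from 0.0192 to 0.0494. The calls of these 11 genes ended without 0 ppb replicate 1 (adjusted p = 0.0595 to 0.165). In all they ended without 5 to 14 of the 16 arrays taken 1 at a time. Without the 2 arrays standing apart those of scarb1, mybpc2a, slc13a1, cpa5, grna.2, ifitm1 and ctsl.1 ended (adjusted p = 0.0584 to 0.0988), and with no filter those of lpin1a, scarb1, mybpc2a, slc13a1 and ifitm1 (0.0502 to 0.0845). Quantile scaling ended fabp2, lpin1a and mybpc2a (adjusted p = 0.067 to 0.0809), median scaling scarb1 and ifitm1 (0.0741 and 0.0904) and normexp slc13a1 (0.14). The hatching enzyme he1.1 rose by 2.02 ± 0.40 (adjusted p = 0.0439), from -0.73 ± 0.86 to 1.28 ± 0.49 (SD, n = 4), a call that ended without 13 of the arrays in turn (adjusted p up to 0.15), without the 2 arrays standing apart (0.111) and with no filter (0.0693). Its values at 40 and 4 ppb were 1.97 ± 0.40 and 2.26 ± 0.40, neither of which passed (adjusted p = 0.103 and 1).

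Few named genes fell at 400 ppb in the fit without the block, 6 against 120 that rose. This lean was not kept with the replicate block, which called 1072 genes. Its called probes were 3269 higher and 2936 lower. The embryonic beta globin hbbe3 fell by 2.01 on the log2 scale (SE 0.27, adjusted p = 0.0051), from 0.94 ± 0.55 to -1.07 ± 0.19 (SD, n = 4), and was lower on 4 of 4 slides. The lens crystallin crybb2 (-1.66 ± 0.30), the tooth and bone matrix gene scpp5 (-0.93 ± 0.19), the glutamate transporter slc1a7a (-0.73 ± 0.13), zgc:113984 (-0.82 ± 0.16) and zgc:173548 (-1.55 ± 0.30, with 2 other probes of the gene going the other way) also fell (adjusted p = 0.027 to 0.0431). The calls of these 5 ended with the median in place of the 75th percentile as the scaling point (adjusted p = 0.0682 to 0.509). They also ended without 0 ppb replicate 1 (adjusted p = 0.08 to 0.151), and in all without 6 to 12 of the arrays in turn. Those of crybb2, scpp5 and zgc:173548 ended without the 2 arrays standing apart (adjusted p = 0.0561 to 0.078), those of scpp5, zgc:113984 and zgc:173548 with no filter (0.0559 to 0.0709) and that of crybb2 with quantile scaling (0.306). The lists of cell cycle genes (-0.14, 40 of 49 lower), the proteasome (-0.11, 37 of 43), erythroid cells (-0.22, 19 of 28) and neurons (-0.12, 27 of 34) passed downward with adjusted p = 0.00139, 0.0219, 0.034 and 0.048. These were adjusted p = 0.622, 0.796, 0.451 and 0.599 with an estimated correlation. The proteasome call ended without 0 ppb replicates 2 and 3 or 400 ppb replicates 1 and 2 (adjusted p = 0.0509 to 0.269, mean -0.113 to -0.0368). The erythroid call ended without 0 ppb replicate 1 (adjusted p = 0.124, mean -0.202), and the neuron call without 0 ppb replicates 1, 2 and 3 or 40 ppb replicates 1 and 2 or 400 ppb replicates 2 and 3 (adjusted p = 0.055 to 0.178, mean -0.148 to -0.0888). The erythroid call also ended without the 2 arrays standing apart (adjusted p = 0.0531, mean -0.144) and with the mean of a gene's probes (adjusted p = 0.133, mean -0.213). That of neurons ended with normexp (0.0852) or no filter (0.0522), and the proteasome mean was -0.0578 without the 2 arrays. In the lens list 35 of 47 genes were lower, by -0.16 ± 0.37 (adjusted p = 0.1, and 0.00242 with the replicate block). Ribosomal proteins gave -0.12 ± 0.10 (adjusted p = 0.109, and 1.07e-05 with the block). Neither passed with an estimated correlation (adjusted p = 0.81 for lens and 0.916 for ribosomal proteins), nor with it and the block (0.358 and 0.592). On 0 ppb replicate 4, which stood apart, the lens and ribosomal lists lay 0.505 and 0.616 above the other 0 ppb arrays. This lowers both means, so the falls rest in large part on that array.

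In all 491 probes were called at 400 ppb, 406 higher and 85 lower, and 9942 had an unadjusted p under 0.05, where evenly spread p-values would give about 5098. They stand for 126 genes, of which 39 were among the 180 tested genes of the exocrine pancreas, intestine, liver, bile acid and xenobiotic lists, 53 on any list and 73 on none. Of the 45 lists 19 passed upward and 4 downward, and 22 did not pass. Besides the thyroid, lens and ribosomal lists these were GABA and glutamate, p53, acetylcholine, pigment cells, heart, fatty acid synthesis, respiratory chain, chromatin regulators, glia, skeletal muscle, cartilage and bone, cholesterol synthesis, interferon, unfolded protein response, lymphoid cells, circadian clock, ear and lateral line, endothelium and dopamine (means -0.11 to 0.06, adjusted p = 0.169 to 0.899). Camera ranks a list against all genes, and for the fatty acid synthesis, skeletal muscle and interferon lists it pointed up while mean and median were below 0. The mean, median and test also differed in sign for the circadian, respiratory chain and dopamine lists.

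With the replicate block 6205 probes were called at 400 ppb, 3269 higher and 2936 lower, and all 491 were among them. For lists, camera with both the block and an estimated correlation left 0 past the threshold at any dose, against 24 at 400 ppb with the block alone and 4 with the estimated correlation alone. Leaving out any of the 8 arrays compared lowered the count, to 137, 213, 288 and 304 without 0 ppb replicates 1 to 4, and to 185, 172, 226 and 288 without 400 ppb replicates 1 to 4. Without the 2 arrays standing apart it was 385. The median change over all probes was -0.098, and 0.034 with median scaling, which raised the share of higher calls from 82.7% to 96.6%. Without 0 ppb replicate 4 the median change was -0.029.

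**Figure D2:**
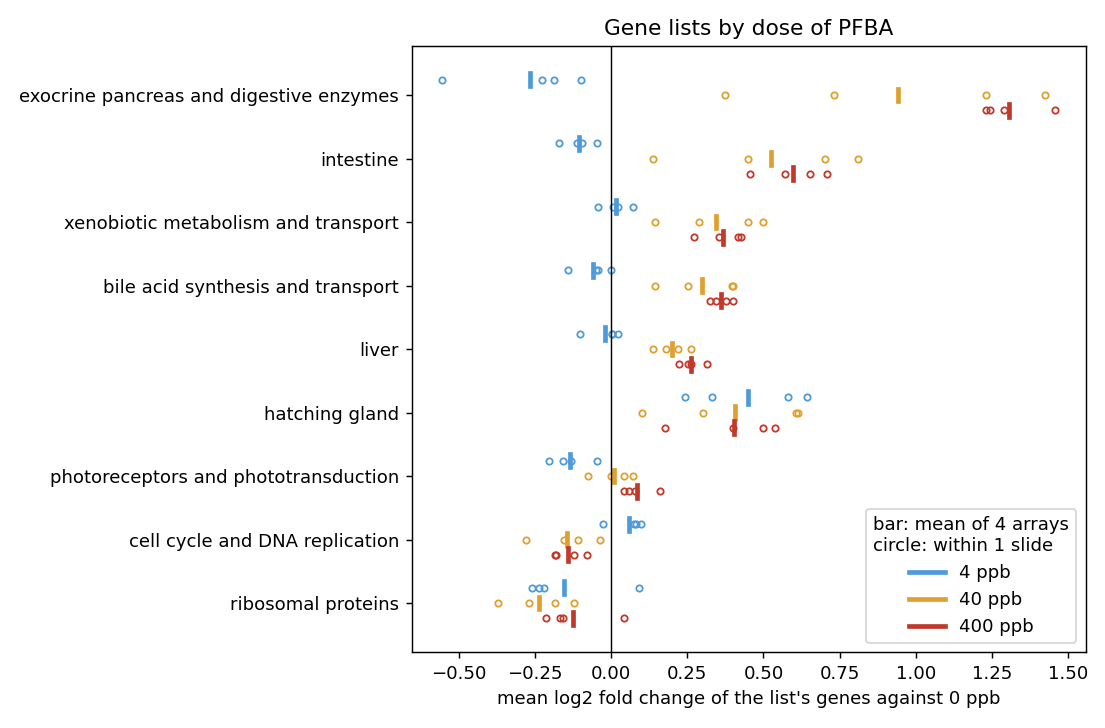
Mean log2 fold change against 0 ppb of 9 gene lists (x axis) at 4, 40 and 400 ppb; bars are means over the 4 arrays of a dose and circles the differences within each slide. The exocrine pancreas list stood at 1.3 at 400 ppb, 0.94 at 40 ppb and -0.27 at 4 ppb.

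**Figure D3:**
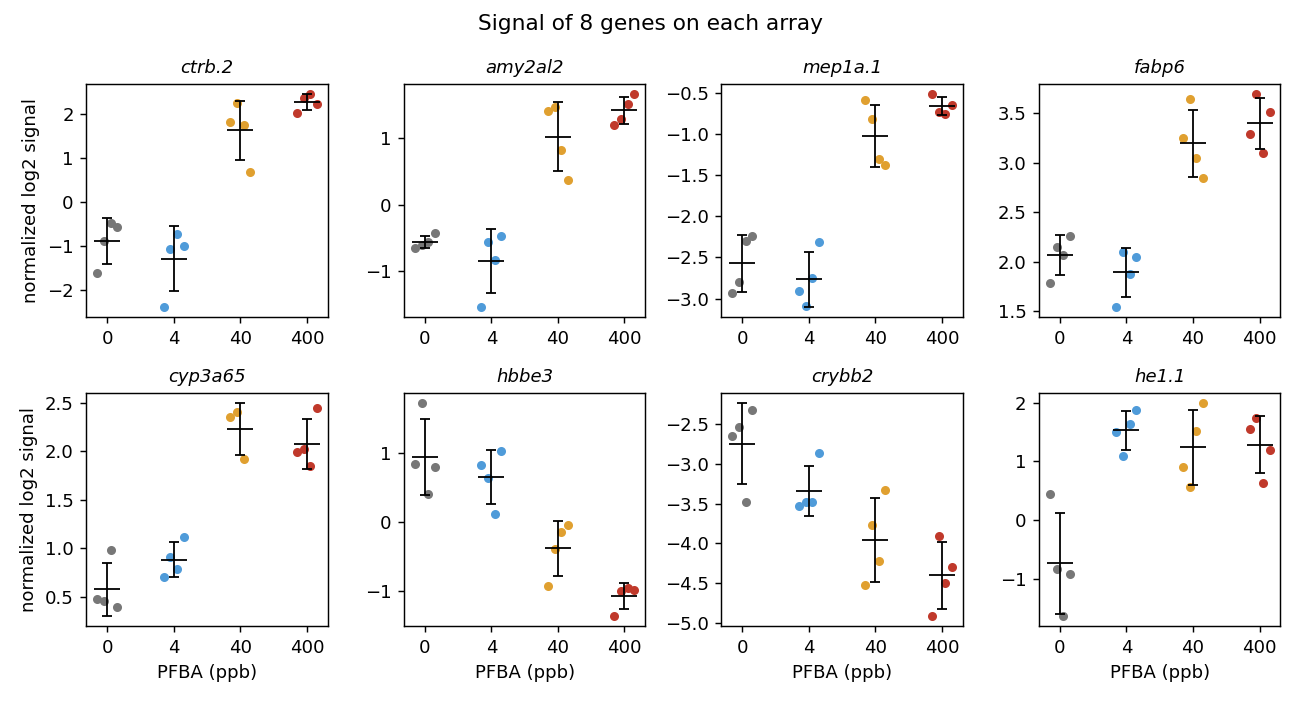
Normalized log2 signal (y axis) of 8 genes on each array against the dose of PFBA in ppb; points are arrays, and bars the mean ± SD of the arrays with a value, at most 4 per dose. For ctrb.2 the mean was -0.88 at 0 ppb and 2.27 at 400 ppb, and for hbbe3 0.94 and -1.07.

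At 40 ppb the same organs led. Exocrine pancreas genes were higher by 0.94 ± 0.64 (26 of 28, adjusted p = 9.37e-33, and 0.035 with an estimated correlation) and intestinal genes by 0.53 ± 0.55 (33 of 37, 4.72e-21, and 0.0319). Xenobiotic genes were higher by 0.34 ± 0.50 (44 of 52, adjusted p = 1.04e-16, and 0.0125 with an estimated correlation), bile acid genes by 0.30 ± 0.41 (10 of 14, 3.4e-06, and 0.035) and kidney and ionocyte genes by 0.19 ± 0.31 (35 of 46, 1.65e-05, and 0.0491). The slides differed more than at 400 ppb, with 1.42, 1.23, 0.73 and 0.37 for exocrine pancreas, 0.81, 0.70, 0.45 and 0.14 for intestine and 0.42, 0.22, 0.21 and -0.10 for kidney. Slides 1 and 4 are those that hold the 2 arrays standing apart. Called over all probes, and adjusted over the list alone in parentheses, were 3 pancreas genes (22 higher, 1 lower), 6 intestinal (15 higher), 4 xenobiotic (15 higher, 1 lower) and 1 bile acid genes (6 higher).

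The chymotrypsinogen ctrb.2 rose by 2.51 ± 0.38 at 40 ppb (adjusted p = 0.0274, 5.71-fold) and c6ast4 by 2.19 ± 0.31 (0.0249). Further, enpp7.1 rose by 2.29 ± 0.39 (0.0442), mep1a.2 by 1.91 ± 0.30 (0.0301) and amy2al2 by 1.58 ± 0.25 (0.0344). The glucuronosyltransferase ugt5a2 rose by 1.71 ± 0.24 (0.0249) and the amine oxidase aoc1 by 1.71 ± 0.28 (0.0378). The fetuin ahsg2 rose by 1.65 ± 0.22 (0.0249) and cyp3a65, measured on 3 of the 4 arrays, by 1.65 ± 0.19 (0.0212). Further rises were those of fabp6 (1.13 ± 0.19, 0.039), dio1 (0.75 ± 0.11, 0.028) and hpdb, an enzyme of tyrosine breakdown (0.92 ± 0.12, 0.0223). The value of hbbe3 was -1.32 ± 0.27 and did not pass (adjusted p = 0.107, and 0.029 with the replicate block). In all 105 probes were called, 93 higher and 12 lower, and 8136 had an unadjusted p under 0.05. The 35 genes they stand for were all higher, 16 of them on a list, and each was also called higher at 400 ppb. With the replicate block 654 genes were called, and more of the called probes were lower (2281) than higher (1601).

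A further 13 lists passed at 40 ppb and lost the call with an estimated correlation. Upward these were liver (0.20, adjusted p = 2.92e-06, and 0.305 with an estimated correlation), fatty acid oxidation (0.11, 0.00158, and 0.527), endocrine pancreas (0.09, 0.00937, and 0.527) and yolk use (0.12, 0.00978, and 0.527). Also upward were lipoproteins (0.14, adjusted p = 0.00158, and 0.558 with an estimated correlation), heat shock (0.21, 0.00978, and 0.447), hatching gland (0.41, 0.0132, and 0.527), oxidative stress (0.10, 0.0145, and 0.723), skin (0.06, 0.0199, and 0.872) and steroid hormones (0.11, 0.0481, and 0.606). Downward they were ribosomal proteins (-0.24, 83 of 84 lower, adjusted p = 0.000593, and 0.965 with an estimated correlation), cell cycle (-0.14, 0.00122, and 0.823) and proteasome (-0.12, 0.0133, and 0.96). With quantile scaling the mean of the ribosomal list was -0.000658 and the test pointed the other way. The block ended the calls of yolk use and skin (adjusted p = 0.0508 for both) and hatching gland (0.0969), and added neurons (0.0474), lens (0.0021) and skeletal muscle (0.00375). With the block and an estimated correlation both, these 3 did not pass (adjusted p = 0.656, 0.413 and 0.538). On 0 ppb replicate 4 the lens and skeletal muscle lists lay 0.505 and 0.308 above the other 0 ppb arrays, which lowers their means. Of those 13, ending with 1 array left out were cell cycle without 40 ppb replicate 1 (adjusted p = 0.363, mean -0.0601) and ribosomal proteins without 40 ppb replicate 3 (adjusted p = 0.184, mean -0.123). So were hatching gland without 40 ppb replicate 4 (adjusted p = 0.118, mean 0.3), lipoproteins without 40 ppb replicate 4 (adjusted p = 0.0613, mean 0.0566), heat shock without 0 ppb replicate 4 (adjusted p = 0.16, mean 0.198) and oxidative stress without 0 ppb replicate 1 or 40 ppb replicate 4 (adjusted p = 0.0672 to 0.123, mean 0.0676 to 0.064). The same held for skin without 0 ppb replicate 3 or 40 ppb replicate 4 (adjusted p = 0.0811 to 0.514, mean -0.0263 to 0.00358), the proteasome without 0 ppb replicates 2 and 3 or 40 ppb replicates 1 and 2 (adjusted p = 0.0559 to 0.724, mean -0.123 to -0.0351) and steroid hormones without 0 ppb replicates 1 and 2 or 4 ppb replicates 2 and 4 or 40 ppb replicates 1 and 3 or 400 ppb replicate 2 (adjusted p = 0.0515 to 0.724, mean 0.117 to -0.014). Without the 2 arrays standing apart all 3 downward calls ended: the cell cycle mean was -0.0294 (adjusted p = 0.203), the ribosomal mean -0.0709 (0.0559) and the proteasome mean 0.0168 (0.802). Heat shock (adjusted p = 0.263, mean 0.182) and steroid hormones (0.484, mean 0.1) ended too. With the block as well so did lipoproteins (adjusted p = 0.0931), steroid hormones (0.309), skin (0.658), hatching gland (0.253) and yolk use (0.261). Normexp ended the proteasome (adjusted p = 0.212) and steroid calls (0.366, mean 0.0562), and quantile scaling that of the proteasome (0.0593, mean -0.0626). Without the 2 arrays the means of fatty acid oxidation, lipoproteins, oxidative stress, endocrine pancreas and skin were higher, at 0.19, 0.25, 0.19, 0.15 and 0.16. The 27 lists that did not pass had means from -0.16 to 0.07 and adjusted p from 0.0686.

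The count at 40 ppb rested on single arrays. It was 0 without 0 ppb replicate 1, 40 ppb replicate 1 or 40 ppb replicate 2, 1 without 0 ppb replicate 2 or 3, and 26 without 0 ppb replicate 4. Every gene call at 40 ppb was thus lost without 0 ppb replicate 1, 40 ppb replicate 1 or 40 ppb replicate 2. The count was 55 without 40 ppb replicate 3, 197 without 40 ppb replicate 4, 48 and 27 without 4 ppb replicates 2 and 3, and 58, 60 and 52 without 400 ppb replicates 1 to 3. With the replicate block 3882 probes were called, 1601 higher and 2281 lower, all 105 among them, and without the 2 arrays that stand apart 0, or 219 with the block as well. Beside these counts of 0 from limma, an unadjusted p under 0.05 was reached by 6306 probes without 0 ppb replicate 1, 11102 without 40 ppb replicate 1, 6192 without 40 ppb replicate 2 and 8578 without the 2 arrays that stand apart. With all arrays 8136 reached it, and 6264 in the unmoderated test.

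At 4 ppb no gene passed. The count of probes called by limma was 0, with 2761 at an unadjusted p under 0.05, where evenly spread p-values would give about 5098. This fit has no slide term, although arrays of the same slide were alike. Its standard errors thus hold slide differences that cancel between doses, so 5098 is not the count that chance gives in it. The lower count is therefore no evidence that genes were unchanged. The smallest adjusted p was 0.0826, the replicate block also called 0, and the unmoderated test gave 3453 at an unadjusted p under 0.05. Among the named genes of small unadjusted p were he1.1 (2.26 ± 0.40), the cathepsin ctslb (1.31 ± 0.31), zgc:174855 (1.51 ± 0.42) and wu:fa26c03 (1.37 ± 0.31) on the higher side. On the lower side were zgc:173548 (-1.23 ± 0.30, with 2 other probes of the gene going the other way), ipp (-0.96 ± 0.28), ccs, a copper chaperone of superoxide dismutase (-0.74 ± 0.21), and the kinase subunit prkar2ab (-0.49 ± 0.14). None of these passed (adjusted p = 1 for each). The genes that rose most at the higher doses had values below 0 at 4 ppb that did not pass, with -0.41 ± 0.38 for ctrb.2, -0.25 ± 0.31 for c6ast4 and -0.79 ± 0.39 for enpp7.1. The median change over all probes was -0.081, and 0.070 with median scaling. Without 0 ppb replicate 4 it was -0.022.

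Of the 45 lists 5 passed at 4 ppb, and 0 with an estimated correlation (adjusted p = 0.941 for each of the 5). Exocrine pancreas genes were lower by -0.27 ± 0.20, 27 of 28 of them (adjusted p = 0.00023, and 0.0128 with the replicate block; slides -0.55, -0.10, -0.23 and -0.19). Without 4 ppb replicate 1 the mean was -0.116 and the call ended (adjusted p = 0.24). Cell cycle genes were higher by 0.06 ± 0.10 (37 of 49, adjusted p = 0.00023; slides 0.10, 0.08, -0.03 and 0.08). The hatching gland list was higher by 0.45 ± 0.90, with 6 of 12 genes higher and 3 called when adjusted over the list alone (adjusted p = 0.000462, 0.0751 with the block, and 0.187 with it without the 2 arrays standing apart). Photoreceptor genes were lower by -0.13 ± 0.15 (47 of 54, adjusted p = 0.000957; 0.0815 without 4 ppb replicate 2, with a mean of -0.101, and 0.0656 with normexp). The photoreceptor mean was -0.0693 without 0 ppb replicate 4. Ribosomal proteins were lower by -0.16 ± 0.10 (79 of 84, adjusted p = 0.0463, and 3.46e-15 with the block), a call that ended without 0 ppb replicates 1 and 4 or 4 ppb replicates 2 and 3 or 40 ppb replicates 1 and 2 or 400 ppb replicates 1 and 2 (adjusted p = 0.0538 to 0.686). The mean was -0.000355 without 0 ppb replicate 4, 0.00721 without 4 ppb replicate 3 and -0.00637 with quantile scaling. The call also ended without the 2 arrays standing apart (adjusted p = 0.683) and with normexp, quantile scaling, no filter or the mean of a gene's probes. With the block xenobiotic metabolism (0.0389), lens (0.0028), skeletal muscle (0.00613) and the respiratory chain (0.00613) passed as well, so that 8 lists did. With the block and an estimated correlation both, these 4 did not pass (adjusted p = 0.827, 0.827, 0.844 and 0.872), nor did the pancreas (0.872) and ribosomal (0.827) lists. Without the block 40 lists did not pass (adjusted p from 0.0784). The means of the lens, skeletal muscle and respiratory chain lists were -0.135, -0.077 and -0.061. On 0 ppb replicate 4, which stood apart, these 3 lists lay 0.505, 0.308 and 0.294 above the other 0 ppb arrays. This lowers their means, so the shifts rest in large part on that array.

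Tested against each other, 400 and 40 ppb differed in no probe called by limma: 0 passed, with 1076 at an unadjusted p under 0.05, 0 with the replicate block, and 913 by the unmoderated test at an unadjusted p under 0.05. Both differed from 4 ppb. Against 4 ppb 445 probes were called at 400 ppb, 419 higher and 26 lower (130 genes, 128 higher), and 146 at 40 ppb, 143 higher and 3 lower (59 genes, all higher). Against 4 ppb, ctrb.2 had adjusted p = 0.00118 at 400 ppb and 0.00998 at 40 ppb, c6ast4 0.00089 and 0.00998, and mep1a.1 0.000979 and 0.00998. With the replicate block the counts were 1953 and 675, all 445 and 146 among them. The count for 400 against 4 ppb fell to 219, 246 and 237 without 4 ppb replicates 1 to 3 and to 224, 251, 267 and 292 without 400 ppb replicates 1 to 4. That for 40 against 4 ppb fell to 27, 61, 30 and 95 without 4 ppb replicates 1 to 4 and to 5, 35 and 94 without 40 ppb replicates 1 to 3, and rose to 294 without 40 ppb replicate 4.

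Over the 4 doses taken as ranks, 1216 probes had a slope that passed, 933 upward and 283 downward (265 genes, 240 and 25), and 482 probes (144 genes) passed the test of any dose. Among the smallest p of the trend were apoda.2 (slope 0.42 log2 per step, adjusted p = 0.00259), tat (0.43, 0.00282), ahsg2 (0.73, 0.00362), hbbe3 (-0.71, 0.00362) and hpdb (0.34, 0.00404). For any dose they were the ectonucleotidase entpd8, si:ch211-240l19.6 and tmem86b (adjusted p = 0.000726 each), c6ast4 (0.000768) and mep1a.1 (0.000798), with changes at 400, 40 and 4 ppb of 1.15, 0.84 and -0.08 for entpd8. The steps were not even: hbbe3 had means of 0.94 ± 0.55, 0.65 ± 0.39, -0.38 ± 0.40 and -1.07 ± 0.19 (SD, n = 4) from 0 to 400 ppb, and cyp3a65 0.58 ± 0.27, 0.88 ± 0.18, 2.23 ± 0.27 and 2.08 ± 0.26, the mean at 40 ppb over 3 arrays. With the replicate block 9325 probes passed for the trend and 3126 for any dose, all 1216 and 482 among them. On the untransformed dose scale the trend called 0 in limma, with 5888 at an unadjusted p under 0.05. The trend count fell to 566 and 747 without 0 ppb replicates 1 and 2 and to 595, 673 and 729 without 400 ppb replicates 1 to 3. The count for any dose fell to 301 without 0 ppb replicate 1, to 305, 308 and 287 without 4 ppb replicates 1 to 3, and to 275, 304 and 301 without 400 ppb replicates 1 to 3.

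Changes at the 3 doses were set against each other over all probes. Probes are not independent, and the doses share the 0 ppb arrays. The correlation of 400 with 40 ppb was 0.656, where unchanged groups simulated against the same controls gave 0.5, and the covariance was 0.0729 against 0.0586. The simulation drew all arrays as independent noise, without slide differences or correlation between probes, so its values are a rough mark only. With the controls split between the doses r was 0.0388 on average (-0.14 to 0.268), and within slides 0.373, 0.603, 0.381 and 0.862. A split sets the controls of 2 slides against a dose read on 4. Slide deviations then enter the 2 changes with opposite signs and lower r, so the split values do not measure how far the doses agree. Within a slide both changes subtract the same 1 control array, which by itself raises r. On slide 4 that array is 0 ppb replicate 4, which stood apart. The values within slides therefore do not measure it either. For 400 with 4 ppb r was 0.606 (covariance 0.06, split controls -0.0475, slides 0.613, 0.546, 0.416 and 0.847). For 40 with 4 ppb it was 0.456 (0.0438, -0.115, slides 0.37, 0.497, 0.407 and 0.883). The last lies under the value of unchanged groups. Leaving out 1 array moved r for 400 with 40 ppb between 0.454 (without 40 ppb replicate 2) and 0.745 (without 0 ppb replicate 2). For 400 with 4 ppb it moved between 0.523 (without 400 ppb replicate 2) and 0.737 (without 0 ppb replicate 2), and for 40 with 4 ppb between 0.206 (without 40 ppb replicate 2) and 0.665 (without 40 ppb replicate 1). Of the probes called at 40 ppb, 91 of the 93 higher and 7 of the 12 lower were also called at 400 ppb, where independent lists would share 0.370 and 0.01. At an unadjusted p under 0.01, 1023 higher and 564 lower probes were shared by 400 and 40 ppb. Independent lists would share 21.7 and 18.4, and unchanged groups, also simulated as independent noise, 159.1 in both directions (mean of 20 draws). The simulated counts here and below are therefore no exact level of chance for these arrays. For 400 and 4 ppb 29 higher and 140 lower were shared (1.35 and 4.39, simulated 157.4) and for 40 and 4 ppb 47 and 164 (0.842 and 4.00, simulated 157.6).

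The authors' deposited tables list 895 probes at 400 ppb (526 higher, 369 lower), 829 at 40 ppb (378 and 451) and 186 at 4 ppb (7 and 179), all with a fold of at least 1.5. At both 400 and 40 ppb stand 352 symbols of the authors' deposited tables, 343 of them in the same direction and 1 in the opposite. In the authors' deposited tables are also 70 at both 400 and 4 ppb, 87 at both 40 and 4 ppb and 64 at all 3 doses. Of the genes of the authors' deposited table matched here, 400 of 428 (93.5%) went the same way at 400 ppb, 355 of 409 (86.8%) at 40 ppb and 44 of 58 (75.9%) at 4 ppb, where the match was by symbol. Of these, the genes of the authors' deposited table called here were 71, 20 and 0, and 254, 183 and 8 had an unadjusted p under 0.05. Over these genes log2 changes in the authors' deposited table and here correlated at 0.889, 0.807 and 0.0997. The tables belong to this series and rest on the same arrays, so the match is no independent evidence. Direction was read on the probe that represents a gene here, which need not be the listed probe. At 4 ppb 179 of the 186 listed probes were lower. Here 2305 probes were lower and 456 higher at 4 ppb at an unadjusted p under 0.05. Such a shared lean can raise the 75.9% without agreement on single genes. At an unadjusted p under 0.05 with a fold of at least 1.5, 3789 probes stood out here at 400 ppb (1500 higher, 2289 lower), 3039 at 40 ppb (1060 and 1979) and 1130 at 4 ppb (77 and 1053). All 3 comparisons share 0 ppb replicate 4, whose dim probes lay 0.93 above the other 0 ppb arrays in the median. Without that array the median change over all probes was -0.029, -0.024 and -0.022 at 400, 40 and 4 ppb. With all arrays it was -0.098, -0.081 and -0.081. The excess of lower probes is therefore not read as an effect of PFBA. Among genes picked from all 3 of the authors' deposited tables, ttr and crybb2 were called here at 400 ppb, while ipp, rev1, tbc1d20, slc5a5, dync1h1 and lsamp were called at no dose. Their log2 changes at 400 ppb ran from -1.33 for slc5a5 to -0.27 for dync1h1. With the replicate block ttr and crybb2 also passed at 40 ppb (adjusted p = 0.0156 and 0.0186).

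None of 6 genes commonly used as references was called at any dose. At 400 and 40 ppb actb1 gave -0.27 ± 0.29 and -0.36 ± 0.29, actb2 -0.21 ± 0.32 and -0.34 ± 0.32. At these doses gapdh gave -0.13 ± 0.37 and -0.28 ± 0.37, tuba1b -0.31 ± 0.19 and -0.24 ± 0.19, rpl13a -0.04 ± 0.21 and -0.16 ± 0.21, and eef1a1l1 0.06 ± 0.13 and -0.05 ± 0.13. With the replicate block actb1, actb2 and gapdh passed at 40 ppb (adjusted p = 0.0295, 0.0404 and 0.029).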

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

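The fits without the 2 atypical arrays, the values of lists beside probes of the same signal and the pairs of arrays left out for the lists lower at 40 ppb were chosen only after the result was seen. The tests of raised signal of dim probes and of a biological difference of these pools were set before. In groups of 4 arrays, 30 of 572 sets of values (5.24%) had 1 array far from the other 3, where chance gives about 5%. The scanner software marked 3.97% of spots as outliers on 40 ppb replicate 1 (0.186% to 0.548% on the other 40 ppb arrays) and 0.332% on 0 ppb replicate 1 (0.0483% to 0.0801%). The lowest signal well above background was 26.2 on 0 ppb replicate 4 and 12.3 to 13.3 on the other 0 ppb arrays.

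The pattern weighed is that 40 ppb replicate 1 and 0 ppb replicate 4, of different dose and slide, stood apart from the other arrays. A candidate explanation is a raised signal of dim probes: the deviation from the group mates fell with the mean signal of the probe on both (Spearman -0.392 for the weaker and -0.645 for the other, over probes). This fall largely restates the larger share of spots well above background on both arrays, so it adds little as a test. For a biological difference of these pools, the list with the largest deviation, lymphoid cells on 40 ppb replicate 1, moved by 0.735 times as much as the median dim probe (0.665 for ribosomal proteins on 0 ppb replicate 4). Both lay under the bound of 1 set to argue against it. The test set list means, over probes of mixed signal, against dim probes alone, so it cannot decide on such a difference. A part carried by lists stays open: ribosomal proteins deviated by 0.616 on 0 ppb replicate 4, where probes of the same signal gave 0.366, and by -0.0419 on 40 ppb replicate 1, and the exocrine pancreas list by 0.446 on 40 ppb replicate 1, where probes of the same signal gave -0.0119. The 2 atypical arrays are a candidate explanation for the lower cell cycle, ribosomal and proteasome lists at 40 ppb, whose means without both were -0.0294, -0.0709 and 0.0168 in place of -0.14, -0.24 and -0.12, and of the 15 other pairs of 1 array at 0 and 1 at 40 ppb 0 brought all 3 below 0.5 times their values when left out. The cell cycle list was also lower at 400 ppb (mean -0.14), and that call held without both arrays, while the proteasome mean at 400 ppb shrank without them.

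Replicate 4 lay apart for the neuron list at 4 ppb (0.0934 against -0.11 to -0.09, as the mean minus the control mean) and at 400 ppb (0.0751 against -0.21 to -0.16), and for the liver list at 4 ppb (0.15 against -0.09 to -0.05) and 400 ppb (0.41 against 0.20 to 0.23). Single genes lay apart as normalized log2 signals, at about the rate of chance. At 0 ppb these were c6ast4 at -1.92 (others -1.22 to -1.13) on replicate 1 and sycn.2 at -0.67 (others -0.11 to -0.07) on replicate 2. Also apart were cyp3a65 at 0.98 (others 0.39 to 0.48) and guca1b at -1.36 (others -1.13 to -1.09) on replicate 3, and replicate 4 gave slc1a7a at -0.92 (others -1.40 to -1.36) and cahz at 3.18 (others 3.42 to 3.44). At 4 ppb they were slc5a5 at -5.64 (others -6.64 to -6.54) on replicate 1 and hspa8b at -1.93 (others -1.20 to -1.12) on replicate 3. On replicate 4 they were crybb2 at -2.87 (others -3.53 to -3.48), ccnb1 at 2.65 (others 2.4 to 2.44), rps8b at -1.82 (others -2.50 to -2.40), slc34a2aas at -2.48 (others -3.05 to -2.96) and grk1a at -3.96 (others -3.47 to -3.41). At 40 ppb pde6ga was at -0.41 (others -0.62 to -0.59) on replicate 2 and sst2 at 0.40 (others 0.52 to 0.53) on replicate 3. At 400 ppb hbbe3 was at -1.35 (others -1 to -0.95) and psmc1a at 3.76 (others 4.26 to 4.35) on replicate 1. Further ones were tdo2b at -1.42 (others -2.30 to -2.16), cldnb at 2.18 (others 2.36 to 2.39) and zgc:174855 at -0.0529 (others -0.81 to -0.69) on replicate 2. The last were grk1a at -3.56 (others -3.24 to -3.19) on replicate 3, and cyp7a1 at 1.05 (others 1.5 to 1.53) and aoc1 at -0.21 (others -0.01 to 0.00) on replicate 4.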

How the results depend on the processing

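The fits without the 2 atypical arrays (0 ppb replicate 4 and 40 ppb replicate 1) were chosen only after the result was seen. All other alternatives were planned. Of 6114 values of named genes under an alternative, 5455 kept direction and side of the threshold, 469 lost the call, 190 gained it and 0 turned. Of 75 gene calls 75 kept it with the replicate block, 71 with quantile scaling, 59 with median scaling, 53 with no filter, 39 without the 2 arrays and 28 to 75 without 1 array. Of 1150 values of lists 979 kept direction and side and 169 lost the call. The test turned for ribosomal proteins at 40 ppb with quantile scaling (mean -0.000658) and at 4 ppb without 4 ppb replicate 3 (mean 0.00721, and -0.391 without 4 ppb replicate 4). The calls of the exocrine pancreas, intestine, xenobiotic and bile acid lists at 400 and 40 ppb held under each alternative run on lists except the block with an estimated correlation together, under which 0 lists passed at any dose. Over the others the pancreas mean at 400 ppb ran from 1.22 to 1.39.

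The rest are probe counts, in the order 400, 40 and 4 against 0 ppb, 400 against 40, 400 against 4 and 40 against 4 ppb unless named. The cause of a change was not tested unless the construction shows it. At an unadjusted p under 0.05 they were 9942, 8136, 2761, 1076, 4785 and 3514. For any dose and the trend they were 5869 and 12301, and for the pairs with a fold of at least 1.5 3789, 3039, 1130, 556, 1753 and 1583. The unmoderated test at an unadjusted p under 0.05 gave 10146, 6264, 3453, 913, 6589 and 3274, and adjusted 149 and 0 for the first 2 and 102 and 0 for the last 2. At an adjusted p under 0.1 there were 912, 227 and 1 against 0 ppb, 254 for 40 against 4 ppb and 2119 for the trend. Fitted on the 2 groups alone, which leaves fewer arrays, 400 against 0 ppb gave 165, 40 against 0 ppb 0 and 40 against 4 ppb 0. Untransformed dose gave 0 for the trend.

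Normexp gave 172 for 40 against 0 and 241 for 40 against 4 ppb. Median scaling gave 43 and 1 for 40 and 4 against 0 ppb, 250 and 48 against 4 ppb and 293 for any dose. No filter gave 317 and 32 against 0 ppb and correlations of 0.468 for 400 with 40 and 0.29 for 40 with 4 ppb. Probes well above background on all arrays gave 177 for 40 against 0 ppb. Trend and robust variances gave 739, 210 and, for 40 against 4 ppb, 249. Array weights gave 1071 and 2 for 400 and 4 against 0 ppb, 892 for 400 against 4 ppb, 818 for any dose and 1980 for the trend.

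The replicate block, which is also the slide, gave 6205, 3882, 1953 and 675 for the 4 comparisons that called any, 3126 for any dose and 9325 for the trend, and 8 lists at 4 ppb. It ended no call of a named gene, and the lists whose call it ended are given beside the results. The scan day as a block gave 2543, 824, 1, 0 (with 3000 at an unadjusted p under 0.05), 1116 and 366, 1408 for any dose and 5130 for the trend. Without the 2 arrays 40 against 0 ppb gave 0, 400 against 40 ppb 1, 40 against 4 ppb 6, and the correlation of 40 with 4 ppb 0.626. With the block as well the counts were 4260 and 219 against 0 ppb, 2 for 400 against 40, 2493 for 400 against 4 ppb, 1801 and 7414 for any dose and the trend, r 0.615 and 9 lists at 4 ppb. With an estimated correlation 4, 5 and 0 lists passed at 400, 40 and 4 ppb, and with fry 6, 5 and 0. Shared probes were 429, 15 and 18 at an unadjusted p under 0.001 and 5017, 1423 and 1493 at 0.05 for 400 and 40, 400 and 4 and 40 and 4 ppb.

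Leaving out 1 array gave 137 to 536, 0 to 197, 0 to 1, 0 to 0, 219 to 492 and 5 to 294 in the order above. It gave 275 to 550 for any dose, 566 to 1175 for the trend. Correlations were 0.454 to 0.745, 0.523 to 0.737 and 0.206 to 0.665 for 400 with 40, 400 with 4 and 40 with 4 ppb, and there were 18 to 23, 16 to 18 and 4 to 10 lists at 400, 40 and 4 ppb. Signal over background limits dim probes: of 101957 kept probes 81629 were well above background on all arrays.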

Other observations

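The tests of order of handling, of fish further along in development, of 1 array deciding the 4 ppb result, of the 2 atypical arrays at 40 ppb, of slide differences in the cell cycle list and of splits within slides for any dose and the trend were chosen only after the result was seen, and the genes in the next sentences were chosen after their values were seen. At 400 ppb gip rose by 1.48 ± 0.18 (adjusted p = 0.00324) and insl5a, like gip a peptide hormone gene, by 1.37 ± 0.20 (adjusted p = 0.00839). The chloride exchanger slc26a3.2 rose by 1.39 ± 0.20 (adjusted p = 0.0069) and the phosphate transporter slc34a2a by 1.44 ± 0.25 (0.0208). The amino acid transporter slc6a19b rose by 1.07 ± 0.15 (0.0069), the glucose transporter slc5a1 by 0.88 ± 0.13 (0.00774) and the aquaporin aqp8a.2 by 1.07 ± 0.18 (0.0174). So did the sialidases neu3.3 (1.19 ± 0.17, 0.00849) and neu3.4 (0.92 ± 0.17, 0.0266). Further rises were those of the uncoupling protein ucp3 (0.96 ± 0.18, 0.0354), the sex hormone binding globulin shbg (0.88 ± 0.15, 0.0164) and crp3 (0.89 ± 0.14, 0.0122). Of these gip (1.23 ± 0.18, adjusted p = 0.0274), slc26a3.2 (1.33 ± 0.20, 0.0274) and slc6a19b (0.88 ± 0.15, 0.0457) also passed at 40 ppb. Not passing at 400 ppb, and chosen in the same way, the pancreas transcription factor ptf1a gave 0.27 ± 0.18 (adjusted p = 0.679) and insulin ins 0.07 ± 0.20 (0.949). Also not passing, the hepatocyte gene fabp10a gave 0.64 ± 0.18 (0.198, and 0.00955 with the replicate block) and cyp1a, the usual target of the aryl hydrocarbon receptor, 0.92 ± 0.50 (0.598, and 0.037 with the block).

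For the rise of digestive organ genes at 400 ppb the atypical 0 ppb replicate 4 is argued against as the source. On it the exocrine pancreas list lay 0.338 above the other 0 ppb arrays, which lowers the change. Without both atypical arrays the mean of that list was 1.389, against 1.3 with all. The other, 40 ppb replicate 1, does not enter this mean, so leaving it out tests nothing here. Signal-dependent scaling or hybridisation is argued against too, since the median of that list lay at the 100 percentile of 10000 random lists matched on mean signal. At 40 ppb the 2 atypical arrays are argued against for the pancreas list, since without both the pancreas mean was 0.914, against 0.94 with all, and slides 2 and 3, which hold neither, gave 1.23 and 0.73, but stay open for the 105 probe calls, of which limma kept 0 without both (8578 at an unadjusted p under 0.05) and also 0 without 10 of the 15 other pairs of 1 array at 0 and 1 at 40 ppb. Order of handling or position on the slide cannot be told apart from dose, since positions followed the dose on 4 of 4 slides. Fish further along in development may be the source and stay open: of 5 stage lists 2 passed that way at 400 ppb (photoreceptors and cell cycle) and 1 the other way (hatching gland), which meets the bound written to exclude this explanation, and with the replicate block the hatching gland call ends (adjusted p = 0.13) while lens crystallins pass the other way (mean -0.16, adjusted p = 0.00242). It was left open after those values were seen, because lists go both ways in either fit and none of these 4 passes with an estimated correlation (adjusted p = 0.622 for photoreceptors and for cell cycle, 0.451 for hatching gland and 0.81 for lens). The lens value also rests in part on 0 ppb replicate 4, an atypical array. There the lens list lay 0.505 above the other 0 ppb arrays, which lowers its mean against 0 ppb.

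At 4 ppb the pancreas and cell cycle lists went opposite to the higher doses. That 1 array decides is a candidate explanation, since 1 of the 16 arrays, 4 ppb replicate 1, ends the pancreas call when left out, and the mean ran from -0.378 to -0.116. Between-gene correlation is another, since neither list passed with an estimated correlation (smaller adjusted p = 0.941). For slide differences the direction within slides was counted: the pancreas list was lower at 4 ppb on 4 of 4 slides and the cell cycle list higher on 3 of 4. Each slide held 1 array of each dose, so a shift shared by the arrays of a slide cancels between doses and is the source of neither. The counts show only how far the replicates went the same way. An effect of the low dose itself stays open, untested beyond these.

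Other splits of the same arrays into groups of the same size were counted with limma. For any dose 1 of 100 drawn splits, the real one, called as many probes (482, highest other 223), and for the trend 1 of 100 (1216, highest other 280). With doses drawn anew only within each slide it was again 1 of 100 for any dose (highest other 5) and for the trend (highest other 14). This is the smallest share that 100 splits can give, and it argues against chance for both counts without excluding it. For pairs of doses 1 of 35 splits called as many for 400 against 0 ppb (491, highest other 0), 40 against 0 ppb (105, highest other 40), 400 against 4 ppb (445, highest other 0) and 40 against 4 ppb (146, highest other 1). Most of these splits break up the slides, and the 8 that part all 4 slides, as the real one does, are too few for a share under 0.05. Among these 8 the highest other was 4 for 40 against 0 ppb and 0 for the remaining pairs. For 4 against 0 ppb and 400 against 40 ppb the real count was 0, which 35 of 35 splits reach whatever their values (highest other 0), so that these splits decide nothing.

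The spike-in slope in the file headers was 0 on 400 ppb replicate 4 and 0.893 to 1.06 on the other arrays; it entered no value here.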
